A study of Homo sapiens with 6 samples.

How the data were processed

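PolyA RNA of NGN2-induced human iPSC-derived neurons was sequenced in 6 libraries, 3 control and 3 PEDS1 knockout. Per the labels' protocols, stranded mRNA libraries were made from 500 ng of total RNA and read as single-end 100 bp reads. The labels give 1 batch for all libraries. Groups and replicate numbers were taken from the sample labels.

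Per the submitters' processing notes, the tools were STAR 2.7.10b and DESeq2 and the genome build was GRCh38. The counting tool and the annotation are not given in the sources used here. The authors deposited a signal value per gene and library, a read count divided by 1 size factor per library. In these deposited normalized counts, 100% of values were whole multiples of the library's step (tolerance 1e-06), so whole reads were recovered. Every listed gene had at least 10 reads in 3 or more libraries. Per the file headers, the authors also gave a log2 fold change, a Wald score and a p-value with its adjusted value for each gene. The adjusted p-value was empty in 1612 genes of the authors' deposited table. A second deposited sheet repeats 344 genes with an absolute log2 fold change of 1 or more and an unadjusted p-value under 0.05. Its standard error column holds a fold in all 239 rows with a negative log2 fold change, and the main sheet's holds one for CALR, so that column was not used.

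Because the sheets hold normalized values, the test planned for raw counts (edgeR) was replaced, as planned for this case, by limma 3.58.1 in R 4.3.3: a linear model of genotype on log2(normalized count + 1), with an empirical Bayes variance trend and Benjamini-Hochberg adjustment over 16625 genes. Fold changes are on this log2 scale, which understates the change of low genes. Gene lists with 5 or more measured members, 48 of 49 fixed before the data were examined, were tested with camera (preset inter-gene correlation 0.01). The planned voom values were replaced by the log2 values with the same variance trend, a choice made after a run without the trend had been seen. The same lists were tested with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Of the lists' genes 1167 were measured.

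Named genes followed a rule fixed before the data were examined: PEDS1, then the 12 largest increases and 12 largest decreases among genes with a symbol, adjusted p under 0.05, a mean normalized count of 100 or more and no overlap between groups, then up to 4 members per list with the smallest adjusted p under 0.05, or 2 members where none passed. Some genes that the rule selects are not reported here. Alternatives chosen in advance were the authors' adjusted p-values, TMM and quantile scaling, mean count filters of 10 and 100, pseudocounts of 0.5 and 5 and stricter thresholds. Also chosen in advance were fry and other correlations or ranks in the set test, a replicate block and leaving out each library. A last one kept only genes whose symbol is not a clone or placeholder name. Alternatives added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, removal of each library's trend on GC content and transcript length (natural splines with 4 degrees of freedom, GENCODE 29 transcripts, 96.5% of genes), and camera without a variance trend and on voom values of the recovered reads. DESeq2 on the recovered reads made the same 2706 calls as the authors' deposited table. A direction was counted as reversed only where one of the settings made a call.

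On simulated reads of 16625 genes with 200 changed, limma recovered 65.5% of genes changed 1.5-fold, 81.2% of those changed 2-fold and 98.7% of those changed 4-fold. Of its calls 8.24% were false, above the nominal 5%. The simulation was not repeated, and with 15 false calls it does not settle whether the excess is more than sampling. Far fewer genes were changed there than the 2269 called in these data, so its recovery does not give the power here. These reads held no trend on GC content. With such a trend added to the simulated knockout libraries, 83.8% of limma's calls were false before its removal and 4.71% after. The size of that trend was set, not fitted to these data, so the false share in these data is not known. The added trend followed the same GC values that the removal uses, so its removal there was built in. It is no check on a bias that those values do not capture. Replicates of a group differed by more than sampling noise in all pairs, so none was counted as a duplicate. The mean squared difference per gene relative to sampling noise (chi-square) was 3.1 to 14.2 among controls and 13.5 to 41.6 among libraries labelled knockout. The highest, 26.3 and 41.6, were the pairs with the library labelled PEDS1 knockout replicate 3. The main test fits the same variance for both groups. The intervals given are bootstrap intervals over genes, or an exact binomial interval for a percentile among genes, and genes are not independent replicates.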

Results

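Gene expression was measured by polyA RNA sequencing in neurons made from human induced pluripotent stem cells (iPSCs) that carry a doxycycline-inducible NGN2 gene, a transcription factor that drives iPSCs into neurons. The series design text places the neurons at day 10 to 14. There were 2 groups of 3 libraries, control and PEDS1 knockout. PEDS1 is the desaturase that makes the vinyl ether bond of plasmalogens, the most abundant ether lipids. The recovered read totals were 25275584, 30887946 and 44573013 in control replicates 1, 2 and 3, and 28773664, 17996634 and 25213127 in the libraries labelled PEDS1 knockout replicates 1, 2 and 3. A total of 16625 genes was tested. At this depth the median standard error of a log2 fold change was 0.09 for genes with a mean normalized count of 100 or more and 0.25 for genes between 10 and 100. In the labels all controls share 1 source name and all knockout libraries share 1, so separate lines or clones cannot be told apart. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

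The targeted gene checks the labels. PEDS1 (ENSG00000240849, chromosome 20, 50118254 to 50153734, minus strand, GRCh38) had 1368.7 ± 27.4 normalized counts in controls and 983 ± 318 in the libraries labelled knockout (SD, n = 3 each). The values were 1360, 1347 and 1399 in controls, 836 and 765 in the libraries labelled PEDS1 knockout replicates 1 and 2, and 1349 in the library labelled PEDS1 knockout replicate 3, which lies within the control range. The log2 fold change was -0.52 ± 0.17 (SE) and missed the threshold (limma adjusted p = 0.0725). An exact two-sided permutation test of the 2 groups gave p = 0.2, where 0.1 is the smallest p that 3 against 3 allow. Without the library labelled PEDS1 knockout replicate 3 the log2 fold change was -0.77 (limma adjusted p = 0.000147). In the authors' deposited table it was -0.48 with an adjusted p of 0.0455. The neighbouring gene UBE2V1, which overlaps a readthrough transcript with PEDS1, had 48.1 ± 7.72 and 56.0 ± 9.87 normalized counts (SD, n = 3 each; limma adjusted p = 0.483). The labels do not say which part of PEDS1 was edited, and an edit that leaves the transcript in place would not lower these counts.

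**Figure D1:**
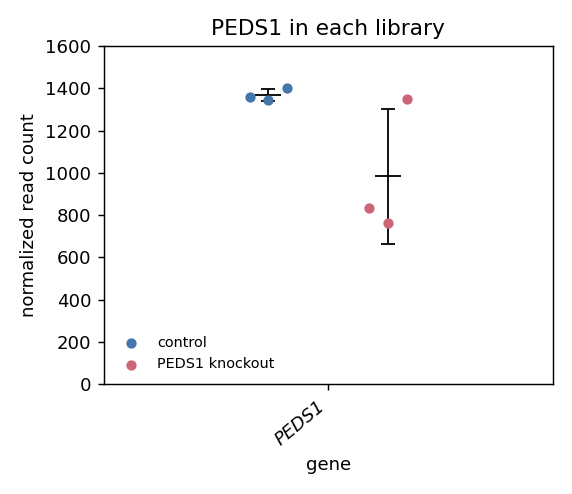
Normalized read count of PEDS1 (vertical axis) in the 3 control and the 3 PEDS1 knockout libraries; points are libraries, bars the mean and 1 SD. The library labelled PEDS1 knockout replicate 3 sits at 1349, beside the controls at 1347 to 1399.

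Of 30 measured genes on the list of the unfolded protein response of the endoplasmic reticulum (ER), 21 fell, chaperones and folding enzymes among them. HSPA5, the main ER Hsp70 chaperone (ENSG00000044574, chromosome 9, 125234853 to 125241330), fell from 23573 ± 698 to 5827 ± 498 normalized counts (SD, n = 3 each), a log2 fold change of -2.02 ± 0.08 (SE; limma adjusted p = 9.38e-07). HSP90B1, the ER Hsp90, fell from 32757 ± 1590 to 7780 ± 712 (SD, n = 3 each), and the lectin chaperone CALR from 27196 ± 532 to 7031 ± 480. SDF2L1 (log2 fold change -3.19), MANF (-2.04), CRELD2 (-1.92), CRELD1 (-1.88) and PDIA4 (-1.72) fell as well. On this list 0 genes rose and 9 did not pass the test, and 23 fell when adjusted over the list alone. The median log2 fold change was -0.85, and the set test (camera) gave an adjusted p of 2.3e-25. With an estimated correlation the adjusted p was 0.0671 without a variance trend and 0.0400 with it. The trend was adopted after a run without it had missed the threshold, so the call with an estimated correlation depends on a choice made after the result was seen. The test on voom values of the recovered reads, added later still, gave 0.0184 with an estimated correlation.

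Of 40 measured ATF4 and integrated stress response genes, 17 fell, 1 rose and 22 did not pass the test (camera adjusted p = 4.62e-05, and 0.431 with an estimated correlation). Of these genes 18 fell and 3 rose when adjusted over the list alone. DDIT3, which encodes the stress transcription factor CHOP, fell by 1.42 ± 0.11 (SE) on the log2 scale, the pseudokinase gene TRIB3 by 1.28 ± 0.07, ATF5 by 1.18 ± 0.07 and CEBPB by 0.80 ± 0.09. CEBPB is also on the list of neighbours of PEDS1 on chromosome 20, and its fall was not tested apart from that place. The count of past-threshold stress response genes was 11 without control replicate 1 and 10 without control replicate 2. Of 27 measured p53 targets, 8 fell and 1 rose, among them the death receptor gene TNFRSF10B (log2 fold change -1.85), the cell cycle inhibitor gene CDKN1A (-1.22) and EDA2R (-2.23), while the set test missed the threshold (camera adjusted p = 0.0548) and fry passed it (fry adjusted p = 5.92e-05). The immediate early list had 5 members lower, ATF3 (-0.40) and JUND (-0.41) among them, and 1 higher, NR4A3 (0.47; camera adjusted p = 0.0416, and 0.431 with an estimated correlation). When trends on GC content and transcript length were removed, the call of JUND was lost and its sign turned, and the immediate early list missed the set test (camera adjusted p = 0.208). The immediate early count of 6 was 11 without the library labelled PEDS1 knockout replicate 3, 2 without control replicate 1 and 1 without control replicate 2. Of 25 listed hypoxia genes, 21 were measured, of which 3 fell, VEGFA by 0.90, and 1 rose.

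**Figure D2:**
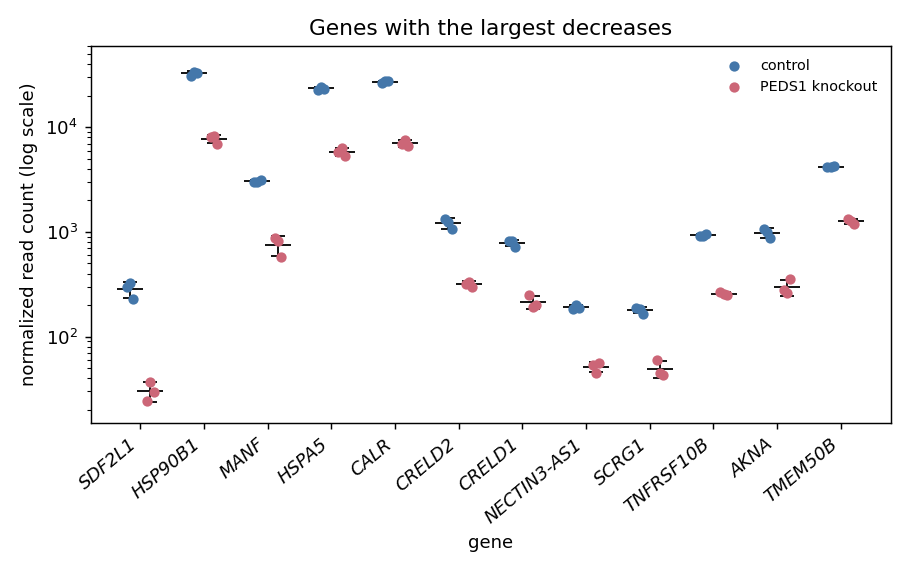
Normalized read counts on a log scale (vertical axis) of the 12 genes with the largest decrease among genes that met the naming rule; points are libraries, bars the mean and 1 SD. The knockout points lie below the control points for each gene.

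Among the genes that met the naming rule, PRLHR, the gene of a peptide hormone receptor, had the largest increase. PRLHR (chromosome 10, 118589989 to 118595699), rose from 173 ± 21.7 to 593 ± 55.3 normalized counts (SD, n = 3 each), a log2 fold change of 1.78 ± 0.12 (SE; limma adjusted p = 2.54e-05). The transcription factor gene SIM1 rose by a log2 fold change of 1.74, SAMSN1 by 1.49, the synaptic vesicle protein gene RPH3A by 1.46, the integrin gene ITGA4 by 1.26, the neuropeptide gene NTS by 1.21, S100A13 by 1.19, IL1RAPL2 by 1.17, PDZRN3 by 1.15 and MYOCD by 1.13. Decreases outside the ER list included NECTIN3-AS1 (-1.87), SCRG1 (-1.86), AKNA (-1.74) and TMEM50B (-1.73). NECTIN3-AS1 is an antisense gene, and how strand was used in counting is not given in the sources used here. In all, 990 genes rose and 1279 fell (limma, adjusted p under 0.05), of which 78 rose and 189 fell by an absolute log2 fold change of 1 or more. The excess of decreases turned into an excess of increases, 1662 against 1464, with trends on GC content and transcript length removed. Groups did not overlap in 37.1% of genes, where chance gives 10%. The total of 2269 was 623 without control replicate 1, 582 without control replicate 2, 1509 without the library labelled PEDS1 knockout replicate 2 and 3577 without the library labelled PEDS1 knockout replicate 3.

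Ether lipid and ferroptosis genes belong to the pathways that the series title names. Over all genes tested, 13.6% passed the threshold. Of 18 measured ether lipid synthesis genes, 3 rose and 0 fell: FAR2, a fatty acyl-CoA reductase that supplies fatty alcohols, rose from 87.2 ± 4.3 to 214 ± 4.66 normalized counts (SD, n = 3 each; log2 fold change 1.28 ± 0.11 SE, limma adjusted p = 0.000119), AGPS by a log2 fold change of 0.32 and PAFAH1B2 by 0.41. The set test missed the threshold (camera adjusted p = 0.319) and fry passed it (fry adjusted p = 0.0192). The count of ether lipid genes was 1 without control replicate 1, 2 or 3. It was 5 without the library labelled PEDS1 knockout replicate 3, of which 4 rose and 1 fell. The gene that fell is not named here. PEDS1, the targeted gene, itself passed the test in that setting (log2 fold change -0.77, limma adjusted p = 0.000147), so this fall is not read as a response of another ether lipid gene. Of 32 measured genes listed as ferroptosis suppressors, 5 fell and 1 rose. HSPA5 is also on this list, FTH1, the ferritin heavy chain gene, fell by 0.49, SLC3A2, a subunit gene of the cystine transporter, by 0.39, and DHCR7 by 0.37 on the log2 scale. CBS (-0.47) and STARD7 (0.28), the others past the test, were chosen after their values were seen. DHCR7 was placed on this list in advance, and whether it acts as a suppressor was not tested here. The fall of DHCR7, 1 of the 5 suppressors counted as lower, is therefore not read as a loss of suppression. DHCR7 also passed as lower without the library labelled PEDS1 knockout replicate 3 and with GC and length trends removed, so those counts include it too. Of 25 measured ferroptosis drivers, 3 rose and 0 fell: ACSL4, which esterifies polyunsaturated fatty acids, by a log2 fold change of 0.50, ACSL1 by 0.42 and NCOA4 by 0.24. Adjusted over the list alone, 3 ether lipid genes rose and 0 fell, 2 suppressors rose and 5 fell, and 4 drivers rose and 1 fell. Neither ferroptosis list passed the set test (camera adjusted p = 0.459 for suppressors and 0.518 for drivers), while fry passed the suppressors (fry adjusted p = 0.0192). Without the library labelled PEDS1 knockout replicate 3, 5 suppressors rose and 7 fell, and 5 drivers rose and 2 fell. Without control replicate 2, 0 suppressors rose and 1 fell, and 2 drivers rose and 0 fell. With GC and length trends removed, 5 suppressors rose and 6 fell, and 5 drivers rose and 2 fell. Among iron handling genes 5 fell, TFR2 by 1.08, and 2 rose, of 24. Among NRF2 targets 3 fell, UGDH by 0.64, and 1 rose, GSTA4 by a log2 fold change of 0.39, of 30.

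Of 24 measured cholesterol synthesis genes, 9 fell, 0 rose and 15 did not pass the test (camera adjusted p = 1.32e-06, and 0.341 with an estimated correlation). Adjusted over the list alone, 12 fell. STARD4, on this list though not the gene of a synthesis enzyme, fell by 1.00 ± 0.07 (SE) on the log2 scale. MVD fell by 0.89 ± 0.15, HSD17B7 by 0.65 ± 0.10 and MVK by 0.45 ± 0.08. The count was 4 without control replicate 1, 3 without control replicate 2 and 5 without control replicate 3. Other lipid lists had members in both directions: 2 rose and 1 fell of 18 cholesterol efflux genes, 4 rose and 2 fell of 27 fatty acid synthesis genes, 4 rose and 6 fell of 33 phospholipid synthesis genes, 1 rose and 3 fell of 28 sphingolipid genes, 4 rose and 1 fell of 33 peroxisome genes, and 1 rose and 4 fell of 23 mitochondrial fatty acid oxidation genes. Without the library labelled PEDS1 knockout replicate 3, 2 cholesterol efflux genes rose and 3 fell, 5 fatty acid synthesis genes rose and 6 fell, 2 sphingolipid genes rose and 6 fell, and 5 fatty acid oxidation genes rose and 5 fell. The balance also turned for cholesterol efflux with TMM scaling (1 rose, 2 fell), for fatty acid synthesis with quantile scaling (3 rose, 4 fell) and for fatty acid oxidation with GC and length trends removed (5 rose, 4 fell). FADS3 fell by 1.00, CPT1A, the carnitine transferase of fatty acid import into mitochondria, by 0.76, and the lysophosphatidylcholine transporter gene MFSD2A by 0.86. ABCD2, a peroxisomal transporter gene, rose by a log2 fold change of 0.74, and the cholesterol exporter gene ABCA1 by 0.75.

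Of 24 measured glycolysis genes 7 rose and 0 fell, led by HK2 (0.71 ± 0.13 SE), PFKFB2 (0.40 ± 0.10), LDHA (0.36 ± 0.09) and PGK1 (0.29 ± 0.07), whose call was lost with GC and length trends removed (limma adjusted p = 0.0583). Camera gave an adjusted p of 0.00317, and 0.431 with an estimated correlation. Adjusted over the list alone, 11 glycolysis genes rose and 2 fell. The glycolysis count was 1 without control replicate 1 or control replicate 2, 2 without the library labelled PEDS1 knockout replicate 1 or 2, and 15 without the one labelled replicate 3. Of 13 mitochondrial-genome genes 2 fell, MT-ND1 by 0.95 and MT-ND2 by 0.80 (camera adjusted p = 0.00023, 0.737 with an estimated correlation, and 0.215 with fry). Neither passed in the authors' deposited table (adjusted p = 0.0521 and 0.102), and MT-ND2 missed with edgeR on the recovered reads (adjusted p = 0.0514). Adjusted over the list alone, 11 mitochondrial-genome genes fell; over all genes the count was 0 without control replicate 1, 2 or 3, 1 without the library labelled PEDS1 knockout replicate 2, 4 without the one labelled replicate 3 and 12 without the one labelled replicate 1. Mitochondrial-genome genes took 2.32% ± 0.094 of reads in controls and 1.52% ± 0.599 in the libraries labelled knockout (SD, n = 3 each), where the values were 2.18%, 1.01% and 1.39% (exact two-sided permutation p = 0.1, the smallest possible). Of 46 nuclear-encoded respiratory chain genes 2 rose, NDUFS1 and NDUFA9 (camera adjusted p = 0.0498, 0.845 with an estimated correlation, and 0.570 with fry), 0 when adjusted over the list alone, and 28 without the library labelled PEDS1 knockout replicate 3. Of 61 ribosomal protein genes 4 fell (camera adjusted p = 6.78e-06, 0.737 with an estimated correlation, and 0.236 with fry), RPS27 by 0.80, and 1 when adjusted over the list alone. The ribosomal protein count was 13 without the library labelled PEDS1 knockout replicate 2, and 1 without the one labelled replicate 1, control replicate 1 or control replicate 2. Their share of reads was 1.48% ± 0.0129 in controls and 1.30% ± 0.182 in the libraries labelled knockout (SD, n = 3 each; exact permutation p = 0.1), and the top 10 genes of each library took 3.71% ± 0.03 and 3.51% ± 0.207 (exact permutation p = 0.3). Of 31 proteasome genes 1 rose, PSMD12, of 38 lysosome and autophagy genes 1 rose and 1 fell, ATP6V1A and ATP6V0A1 (0 and 1 when adjusted over the list alone), and of 19 heat shock genes 3 rose, BAG3, HSPH1 and DNAJB4, and 1 fell, HSF1 (camera adjusted p = 0.0345, 0.724 with an estimated correlation, and 0.101 with fry). The calls of HSPH1 and HSF1 were lost with GC and length trends removed (limma adjusted p = 0.222 and 0.0964). Without the library labelled PEDS1 knockout replicate 3, 7 proteasome genes rose and 0 fell, 5 lysosome and autophagy genes rose and 5 fell, and 9 heat shock genes rose and 1 fell, while without control replicate 2 no heat shock gene passed the limma test.

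Neuronal markers moved in both directions. Of 35 pan-neuronal markers 5 rose, ELAVL4 by a log2 fold change of 0.44, and 3 fell, GPM6A by 0.40. The vesicular glutamate transporter gene SLC17A7 rose by a log2 fold change of 0.55, in a glutamatergic list with 7 of 30 higher and 3 lower. Of 11 measured GABAergic and other transmitter markers 5 rose, among them CALB2 (1.30), DDC (1.01), CALB1 (0.95) and CHAT (0.49), and 1 fell (camera adjusted p = 0.0416, and 0.550 with an estimated correlation). Of 25 peripheral and cranial neuron markers 7 rose, GFRA1 by a log2 fold change of 0.65, and 3 fell, the tachykinin gene TAC1 by 1.21. Presynaptic genes had 8 of 46 higher and 4 lower, with VAMP1 at 0.83, and postsynaptic genes 3 of 38 higher and 3 lower, among them CNTN4 at -1.71. Axon guidance genes had 6 of 43 higher and 6 lower; UNC5B, a netrin receptor gene, fell by 1.66. Voltage-gated channels had 3 of 40 higher and 1 lower. Without the library labelled PEDS1 knockout replicate 3, 7 glutamatergic markers rose and 8 fell, 4 channel genes rose and 6 fell, 13 pan-neuronal markers rose and 5 fell, 4 postsynaptic genes rose and 6 fell, and 8 axon guidance genes rose and 11 fell. With GC and length trends removed, 8 glutamatergic markers rose and 7 fell, and 9 channel genes rose and 5 fell. Pan-neuronal markers had 3 higher and 4 lower with TMM scaling, and 3 higher and 5 lower with quantile scaling. Of 47 clustered protocadherins 6 rose and 1 fell (camera adjusted p = 0.0102, 0.758 with an estimated correlation, and 0.245 with fry). PCDHGB4, PCDHGC3 and PCDHGC4, all among those that rose, overlap and end at the same base, 141512979 on chromosome 5. How reads in shared stretches were counted is not given in the sources used here, so these increases may not be separate. Of 34 zinc finger genes 3 rose and 1 fell (camera adjusted p = 0.0270, 0.737 with an estimated correlation, 0.202 with fry, and 0.577 with GC and length trends removed). Without control replicate 1 or control replicate 2 the protocadherin count was 2 or 1 and the zinc finger count 0, and the protocadherin count was 11 without the library labelled PEDS1 knockout replicate 1 or 3.

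Markers of other cell types were measured beside these groups. Of 19 neural progenitor markers 6 rose, OTX2 by a log2 fold change of 0.90 and TNC by 0.87, and 2 fell (camera adjusted p = 0.0270, and 0.463 with an estimated correlation); the count of 8 was 5 without control replicate 1 and 4 without control replicate 2. Of 12 pluripotency markers 5 rose, LIN28A by a log2 fold change of 1.08, and 1 fell, SOX2 by 0.47. Of 20 mesenchymal markers 6 rose, SPARC by a log2 fold change of 0.72, and 3 fell, TAGLN by 1.00. TOP2A (1.04) and TPX2 (0.49) rose among 26 cell cycle genes. Astrocyte markers had 1 of 11 higher and 1 lower, oligodendrocyte markers 2 of 8 higher, neural crest markers 1 of 7 higher and 1 lower, and FLT1 rose among the 2 measured endothelial, blood and microglia markers. None of 7 epithelial and early germ layer markers and none of 5 HOX genes passed the limma test at adjusted p under 0.05. Interferon genes had 0 of 16 higher and 2 lower, with IRF1 at -1.48, metallothionein and zinc genes 1 of 8 higher and 3 lower, and imprinted genes 4 of 18 higher and 1 lower, with PEG10 at 0.69. Of 21 neighbours of PEDS1 on chromosome 20, SALL4 rose and CEBPB fell, and of 14 genes of 20q11.21, a region often gained in iPSCs, TPX2 rose and HM13 fell, a call lost with GC and length trends removed (limma adjusted p = 0.182). The 35 lists that missed the set test had camera adjusted p-values from 0.0548 to 0.980, and 10 of them passed fry, with adjusted p-values up to 0.0388. Summed over the 49 lists, with genes on several lists counted in each, 128 members rose and 143 fell, against 162 and 192 when adjusted over the list alone. Of the 47 lists with a member past the test, the count moved by over 1.5 times in 40 without control replicate 1, in 42 without control replicate 2, in 13 without control replicate 3, and in 12, 14 and 21 without the libraries labelled PEDS1 knockout replicates 1, 2 and 3.

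**Figure D3:**
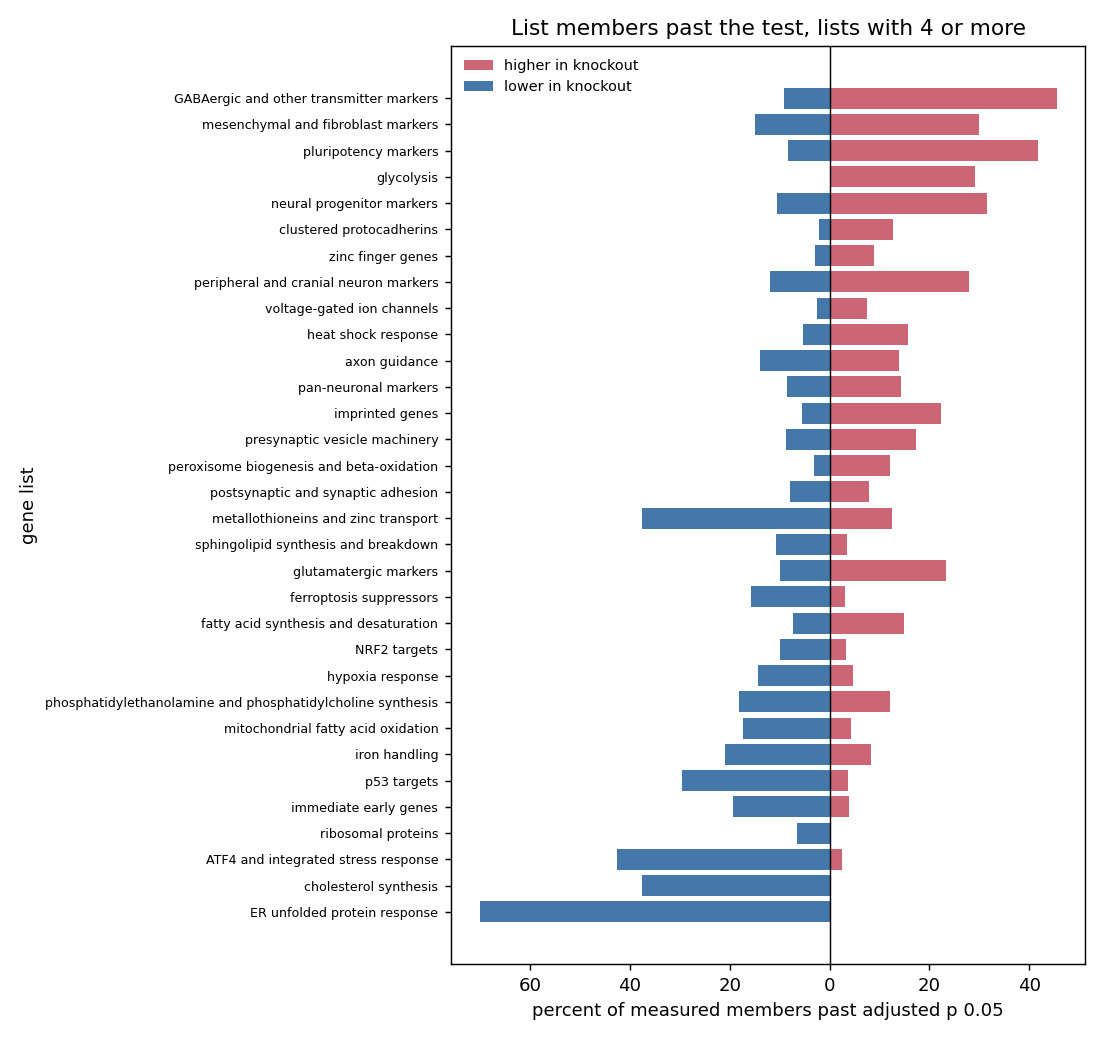
Percent of each list's measured members past adjusted p 0.05 (horizontal axis), higher in the knockout to the right and lower to the left, for lists with 4 or more such members, ordered by median log2 fold change. The ER unfolded protein response list, with 21 of 30 members lower and 0 higher, is at the bottom.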

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

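The settings named below as added were chosen after the data were seen. The count of 2269 genes ranged from 582 to 3577 when each library was left out, and was 640 at adjusted p under 0.01 and 267 with an absolute log2 fold change of 1 or more, both stricter by construction. It stayed within 1.5 times of 2269 under the other settings, from 1560 with a replicate block to 3126 with GC and length trends removed (added), and was 2247 with edgeR on the recovered reads and 2314 with RLE factors (added). The log2 fold change of PEDS1 ranged from -0.77 to -0.37 with 1 library left out. It passed the threshold in the authors' deposited table (-0.48, adjusted p = 0.0455), in DESeq2 on the recovered reads (-0.48, added) and with GC and length trends removed (-0.63, adjusted p = 0.00541, added); over all alternatives its adjusted p ranged from 0.000147 to 0.197.

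The 13 lists past the set test became 1 with an estimated correlation, 5 with a preset of 0.05, 0 with an estimated correlation and no variance trend (added), 12 with voom values and 1 with these and an estimated correlation (both added), and 8 to 12 with 1 library left out, the lowest without control replicate 3 or the library labelled PEDS1 knockout replicate 2. Fry passed 17 lists, of which 7 were among the 13. List members past the test, 251 in all, ranged from 98 to 412 with 1 library left out. Of 167 genes that the naming rule selects and that passed, 83 kept their call under every alternative run for them apart from the stricter thresholds, 16 lost it with GC and length trends removed (added), 25 with a replicate block and 5 to 79 with 1 library left out. Quantile scaling ended 6 of these calls, those of NCOA4, GSTA4, HSPH1 and LDHA among them. The balance of increases and decreases turned in 4 of 47 lists without the library labelled PEDS1 knockout replicate 3 and in 0 to 2 without each other library. JUND turned from -0.41 to 0.042 with GC and length trends removed. The 12 largest increases and 12 largest decreases stayed past the test under all 19 alternatives run for them, and the ER list had 21 to 28 members past it. With 1 library left out, differences between groups in the shares of reads ranged from -1.12 to -0.532 points for mitochondrial-genome, -0.253 to -0.0769 for ribosomal-protein (-0.178 with all) and -0.316 to -0.117 for the top 10 genes. The smallest ribosomal-protein and top 10 values came without the library labelled PEDS1 knockout replicate 3, the largest top 10 value without the one labelled replicate 1. The cause of these changes was not tested.

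No pairing of libraries by replicate number was seen: same-numbered libraries' deviations correlated at -0.12, 0.0148 and -0.0614. These values do not settle whether same-numbered libraries were prepared together. With a replicate block the count was 1560 (698 higher, 862 lower), 10 lists passed and PEDS1 had -0.52.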

Other observations

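The test of mesenchymal markers, the test of the number of lines and both tests on the library labelled PEDS1 knockout replicate 3 were chosen after the results they address were seen.

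The largest pattern is the fall of ER chaperones. A trend on GC content and transcript length as the whole cause is argued against: with it removed, the median log2 fold change of the list was -0.90 (95% bootstrap interval -1.52 to -0.57, 30 genes), against -0.85 before. A loss of mesenchymal cells, which are rich in secretory chaperones, is argued against by their markers. Their median log2 fold change was 0.23 (95% bootstrap interval -0.26 to 0.63, 20 genes). Of these markers 6 rose and 3 fell, and some were low, COL1A2 at 16.7 normalized counts in controls, which limits the argument. An effect of the PEDS1 genotype was not tested apart from a difference between the lines or cultures. With 1 source name per genotype in the labels these cannot be told apart.

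PEDS1 stood at the control level in the library labelled PEDS1 knockout replicate 3. A control library or control cells under that label are argued against: over 3570 of the 3577 genes called without it, with PEDS1 and genes kept out of gene-level reporting set aside, its median position between the control mean (0) and the other knockout libraries (1) was 0.85 (95% interval 0.825 to 0.871), while PEDS1 was at 0.027. A bias of that library towards long 3' UTRs may contribute: the PEDS1 excess of 0.75 (log2) lay at percentile 96.5 of the 200 genes nearest in 3' UTR length and GC content (95% interval 92.9 to 98.6), which does not decide it, and their median excess was 0.28. How the knockout was made was not analysed here.

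Genes that rose had a median transcript GC content of 43.9%, those that fell 58.0% and the rest 48.3%. A trend on GC content and length as the whole cause of the calls outside the ER list is argued against, since 80.5% of 2206 such genes were called the same way with it removed. It may account for some of the rest and for part of the fold in calls that were kept. With it removed, calls ended as log2 fold changes shrank, from -0.41 ± 0.09 (SE) to 0.042 ± 0.12 in JUND, -0.46 ± 0.12 to -0.16 ± 0.06 in HSF1, 0.25 ± 0.07 to 0.12 ± 0.06 in HSPH1, 0.29 ± 0.07 to 0.18 ± 0.06 in PGK1 and -0.25 ± 0.07 to -0.10 ± 0.05 in HM13. Calls that were kept changed in size too. With the trend removed, CEBPB moved from -0.80 to -0.44 and AGPS from 0.32 to 0.14, while SLC17A7 moved from 0.55 to 0.71. The standard error of AGPS also shrank, from 0.09 to 0.04, and the count of all calls rose from 2269 to 3126. A kept call therefore does not show an unchanged fold.

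Each of the 10 splits of the 6 libraries into 3 and 3 was tested, too few for a share under 0.05. For genes 1 split, the real one, gave as many (2269, highest other 0), and likewise for list members 1 (251, highest other 0). Every other split puts both genotypes in each group, so real differences between genotypes widen the spread there. The 0 calls of those splits are therefore no measure of chance. For gene lists 3 splits gave as many as the real 13, and the highest other gave 17, so the number of lists past the preset-correlation test carries little weight here.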
